A study of Mus musculus with 6 samples.

How the data were processed

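Single-cell RNA was measured in 6 libraries of the mouse 4T1 mammary carcinoma model, 3 labelled with a control short hairpin RNA (shNC) and 3 labelled with a hairpin against Pgk1 (shPgk1). Per the labels' protocols, 4T1 cells were transduced with lentivirus for 48 h and selected with puromycin at 2 µg/mL for 7 days, and suspensions with a viability above 80% were loaded on a droplet platform that attaches unique molecular identifiers (UMIs). The values used here are raw UMI counts per gene and barcode, deposited as 1 matrix per library. Per the submitters' processing notes, PISA 0.12 and Seurat 4 were used and GRCh38, also called hg38, was named as the genome build. The gene names in the matrices are mouse names, and 27957 of the 28649 names (97.6%) were found in the GENCODE M21 mouse annotation, so the build and annotation behind the counts are not given in the sources used here. The aligner and the treatment of reads that match several loci are also not given in the sources used here. Columns belonging to other samples numbered 0.

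Samples were placed in groups by their titles. The labels number the libraries 1 to 3 in each group and describe 3 biological replicates, but nothing says that they came from separate animals or cultures, so p-values measure the spread between these 6 samples, whether technical or biological. Each pair of libraries differed beyond sampling noise, with a chi-square per degree of freedom between 24.1 and 273 over genes with at least 20 counts, so no pair was treated as repeat deposits of 1 library. This does not show that the libraries are independent biological replicates.

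The matrices held 42902 barcodes, the shallowest with 1001 UMIs. Cells with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which left out 643 barcodes. Doublets were scored with Scrublet through scanpy 1.11.5 (expected rate 0.06). The threshold that Scrublet set by itself marked 1 cell in each of 4 libraries, so a limit of 0.25 on the score was used in every library, a choice made after the scores were seen, and 825 barcodes were left out. The 41434 kept cells held between 95.8% and 97.2% of each library's counts. In Python 3.11.15, 2000 variable genes were chosen with the library as a batch (mitochondrial genes and the ribosomal-RNA-like genes Gm42418 and AY036118 excluded), reduced to 30 principal components, joined to 15 neighbours and clustered with leidenalg 0.10.2 at a resolution of 0.5 (seed 1), which gave 16 clusters.

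Clusters were named from fixed marker lists of 19 cell types. A cluster took a name when at least 3 markers of that type had a log2 fold above 1 against the mean of the other clusters (5 CPM added, CPM being counts scaled to a common library total) and the runner-up type reached at most 0.5 of the mean marker fold of the best type. The leading 10 genes of each cluster were checked against the name. Monocyte-like and macrophage-like clusters were joined after they were seen, as were T-like and NK-like clusters. Clusters 2, 13 and 15 stayed unnamed. Classes with at least 20 kept cells in each library were tested, which gave 7 classes. The share of cells in a class was compared by a two-sided exact permutation test of the 6 shares, with Benjamini-Hochberg adjustment over classes. With 3 libraries against 3 this exact test cannot go below p = 0.1.

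For gene tests, raw counts were summed per library over all kept cells or over the kept cells of a class, since cells are not replicates. The sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, robust, TMM normalization, filterByExpr, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 folds are libraries labelled shPgk1 over shNC, with the standard error taken as the fold divided by the square root of the F statistic. A term for the difference between classes was fitted over epithelial tumour-like and monocyte or macrophage-like sums with library as a term. A fixed set of 27 gene lists was tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. The count of list members past the threshold is given over all genes tested and adjusted over the list alone.

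Genes were named by a fixed rule. The rule, the marker lists, the gene lists and all settings below that are not said to be added later were chosen before the data were examined. Pgk1 was always given. In all cells and in epithelial tumour-like cells these were the 10 largest rises and 10 largest falls, and in other classes 5 and 5, among genes past the threshold with a mean of at least 20 CPM and with all libraries of a group above all of the other. Gm-numbered, Rik and ribosomal pseudogene names were left out. For lists, up to 4 tested members with the smallest p were named. Another gene is not reported here by name, though list counts and list tests include it. Gm14015, Xist and other transcripts seen in few libraries were chosen after their values were seen.

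Free RNA, which reaches every droplet from broken cells, was estimated per class and library as the median level of other types' markers (at least 20 CPM) relative to the whole library. A gene was called near the free-RNA level when its mean in a class was below 0.5 of its mean over all cells. This limit lies above these median estimates, at most 34.9% of the library level. Such a gene can thus also be expressed in the class itself. Markers of single types reached more, with monocyte or macrophage markers at 61.2% in neutrophil-like cells of library 3 labelled shPgk1. A gene above the limit is therefore not shown to be clear of free RNA. A subtraction of the estimated free RNA, a fit without genes near that level, and fits within clusters 0, 1, 4 or 5 alone were added after the data were seen. Other settings were DESeq2 1.42.0, relative log expression normalization, no gene filter, the replicate number as a block, each library left out in turn, other cell filters, doublets kept, genes listed in all 6 libraries only (22576), thinning to the smallest library, a resolution of 1.0, and an edgeR test of cell numbers. The other normalizations moved the median log2 fold over all genes by at most 0.1.

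The edgeR step was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. A further small set of genes, shifted less for a test of lists, was counted neither as changed nor as unchanged. It recovered 15% of 1.5-fold and 64% of 2-fold changes in all cells (19518 genes), 28% and 68% in epithelial tumour-like cells (16314 genes), and 21% and 58% in monocyte or macrophage-like cells (15613 genes), with 20, 9 and 9 unchanged genes called. In T or NK-like cells it recovered 22% and 65%, in fibroblast-like cells 16% and 62%, and in neutrophil-like cells 7% and 41%. There 16, 10 and 4 unchanged genes were called. Dendritic-like cells gave 4% and 42%, and endothelial-like cells 4% and 43%, with 5 unchanged genes called in each. Unchanged genes were a larger share of these simulated calls than the adjusted p threshold aims for, most clearly in all cells and T or NK-like cells. The real calls can thus include more unchanged genes than that threshold implies. Library totals lay between 78778073 and 128933960 counts, and the summed counts of a class between 144277 in neutrophil-like cells and 73831770 in epithelial tumour-like cells. Intervals on shares are Wilson 95% intervals, which cover counting error only.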

Results

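Droplet single-cell RNA-seq counts were examined in 6 libraries from the 4T1 model. 4T1 is a mouse mammary carcinoma line used as a model of triple-negative breast cancer. There were 3 shNC control libraries and 3 libraries labelled shPgk1. Pgk1 encodes phosphoglycerate kinase, a glycolytic enzyme, and the series title ties it to the p65 subunit of NF-kB and to M2-like macrophages. Total counts were 113157507, 78778073 and 91676105 in shNC libraries 1 to 3. They were 111982862, 116429830 and 128933960 in libraries 1 to 3 labelled shPgk1. After filtering, 7545, 6104 and 6686 cells were kept in shNC and 6567, 7274 and 7258 in libraries labelled shPgk1. The median depth per cell was 9018 ± 928 UMIs in shNC and 11127 ± 666 UMIs in libraries labelled shPgk1 (mean ± SD of library medians, n = 3 and 3). The two-sided exact permutation test gave p = 0.1, the smallest possible here. Median genes per cell were 2324 ± 174 and 2620 ± 139 (exact permutation test, p = 0.1). The median mitochondrial share was 0.818 ± 0.109% and 0.897 ± 0.0279% (exact permutation test, p = 0.4). Ribosomal-RNA-like genes took 9.45, 11.8 and 11.2% of counts in shNC and 8.69, 8.23 and 7.83% in libraries labelled shPgk1. The lincRNA Gm14015 stood apart between the groups, at 37.6, 22.4 and 21.9 CPM in shNC and at 0.0652, 0.213 and 0.0241 CPM in libraries labelled shPgk1.

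The labels describe 4T1 cells, and the libraries held tumour-like cells together with immune and stromal classes. Epithelial tumour-like cells fell into cluster 0 (7607 cells, led by Tiam2, Efna5 and Hmga2) and cluster 1 (8842 cells, led by Krt8, Wfdc2 and Prkg2). Monocyte or macrophage-like cells fell into cluster 4 (4687 cells, led by Slc7a2, Ly6i and Ccl5) and cluster 5 (7582 cells, led by Arg1, Mmp12 and Pf4). A small cluster 12 of the class (252 cells, led by Cd163, Ccl8 and Retnla) stood beside them. T or NK-like cells made up clusters 3 and 10, led by the granzymes Gzmc and Gzmf and by Foxp3. Further classes were neutrophil-like (S100a9, S100a8 and Camp), fibroblast-like (Cpxm1, Crabp1 and Cxcl14) and conventional dendritic-like (Ccl17, Ccl22 and Timd4). Smaller ones were endothelial-like (Plvap, Gpihbp1 and Egfl7), mast or basophil-like (Mcpt1, Mcpt2 and Tpsab1) and pericyte or smooth muscle-like (Rgs5 and Higd1b). Free RNA was measurable in every class. By the median over types, markers of other cell types stood at 14.8 to 21.8% of the library level in epithelial tumour-like cells. They stood at 16.6 to 22.0% in monocyte or macrophage-like cells and at 24.0 to 34.9% in neutrophil-like cells.

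Pgk1 itself was not lower in the libraries labelled shPgk1, so these libraries are named by their label throughout. The gene lies on chromosome X, 106187100 to 106203699 on the plus strand (GRCm38, GENCODE M21). It stood at 342, 329 and 310 CPM in shNC and at 331, 331 and 361 CPM in libraries labelled shPgk1 over all cells. The log2 fold was 0.06 ± 0.07 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.593). In epithelial tumour-like cells it stood at 276, 224 and 207 CPM in shNC and at 251, 314 and 352 CPM in libraries labelled shPgk1. The log2 fold there was 0.37 ± 0.15 (0.07 to 0.68 at 2 standard errors to each side, edgeR adjusted p = 0.113). Within cluster 0 the fold was 0.21 ± 0.14 and within cluster 1 it was 0.02 ± 0.10. Monocyte or macrophage-like cells held 430 ± 26.6 CPM in shNC and 430 ± 11.1 CPM in libraries labelled shPgk1 (n = 3 and 3). In the other 5 classes tested the log2 fold lay between −0.11 ± 0.11 in fibroblast-like and 0.09 ± 0.17 in endothelial-like cells. Each value rested on 26131 to 43513 Pgk1 counts per library over all cells and on 6260 to 24012 in epithelial tumour-like cells. How reads shared between Pgk1 and its near-identical copies were counted is not given in the sources used here.

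**Figure D1:**
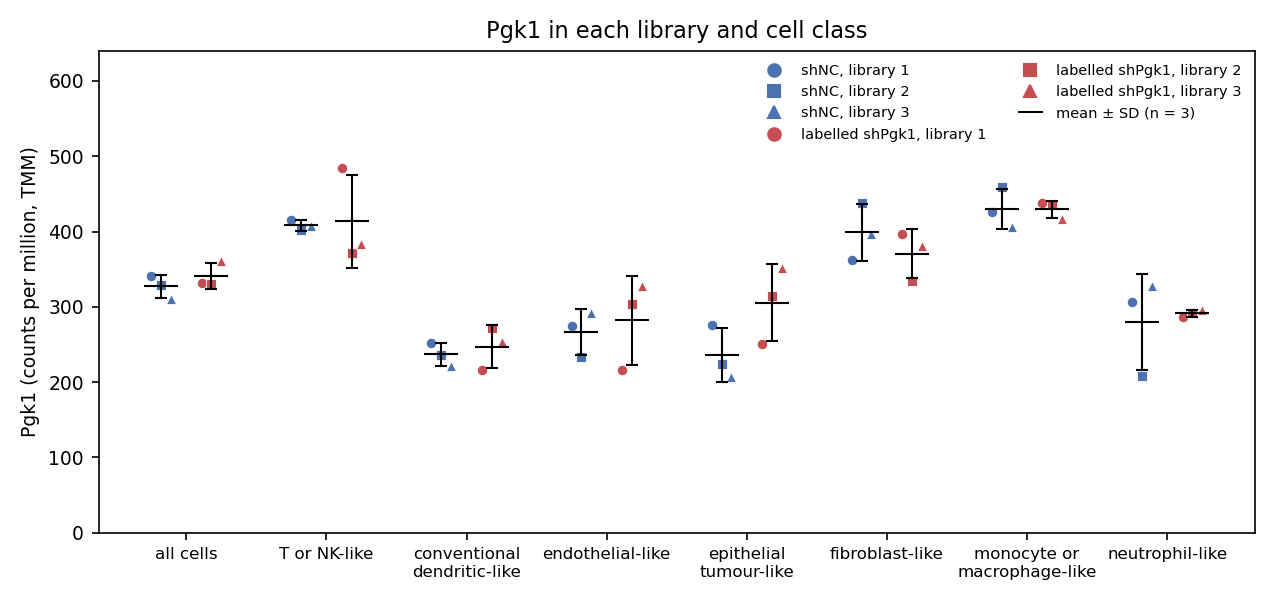
Pgk1 in CPM (TMM-scaled, linear axis from 0) for each library, over all cells and in each class tested; symbols are libraries, and bars are the mean ± SD of 3 libraries. The libraries of the 2 groups overlap in all cells (310 to 342 CPM in shNC, 331 to 361 CPM in libraries labelled shPgk1) and in epithelial tumour-like cells (207 to 276 and 251 to 352 CPM).

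The first comparison asked whether the makeup of the cell suspension differed between the groups. Epithelial tumour-like cells made up 26.3, 31.7 and 39.5% of kept cells in shNC and 44.9, 48.8 and 46.7% in libraries labelled shPgk1. The means of 32.5 ± 6.60 and 46.8 ± 1.99% differed by 14.3 percentage points. Within this class, the share of cluster 1 among kept cells differed by 15.4 points (exact permutation test, p = 0.1). That of cluster 0 differed by −1.08 points (exact permutation test, p = 0.8). Monocyte or macrophage-like cells made up 35.0 ± 1.64% and 25.7 ± 4.32%, a difference of −9.24 points. Neutrophil-like cells made up 5.65, 5.11 and 3.87% in shNC and 0.944, 2.87 and 2.76% in libraries labelled shPgk1. Their median depth was 1717.5 UMIs, near that of the shallowest deposited barcodes, a limit this share can depend on. Fibroblast-like cells made up 5.83 ± 0.960% and 3.59 ± 0.908%. In each of these 4 classes no library of a group overlapped the other group. The exact permutation test gave p = 0.1, the smallest that 3 against 3 allow (adjusted p = 0.25 over 10 classes, unnamed cells counted as 1). T or NK-like cells stood at 7.48 ± 0.685% and 6.22 ± 1.65% (exact permutation test, p = 0.3). Conventional dendritic-like cells stood at 2.02 ± 0.516% and 1.53 ± 0.219% (exact permutation test, p = 0.3), and endothelial-like cells at 1.24 ± 0.459% and 0.910 ± 0.427% (exact permutation test, p = 0.2). Mast or basophil-like cells stood at 0.270 and 0.200%, and pericyte or smooth muscle-like cells at 0.501 and 0.350%. Unnamed cells stood at 10.3 ± 4.54% and 12.5 ± 1.85% (exact permutation test, p = 0.6). For tumour-like cells counting error was small beside the spread of libraries, which was not so for every small class. The nearest pair of tumour-like shares, shNC library 3 and library 1 labelled shPgk1, had Wilson 95% intervals of 38.3 to 40.6% and 43.7 to 46.1%. At a clustering resolution of 1.0 the fibroblast-like difference went from −2.24 to −0.19 points (exact permutation test, p = 0.8). The class then held 545 cells, against 1948 in the main clustering. A cluster of 1403 cells with 7 of 8 fibroblast markers raised stayed unnamed at that resolution, so these differences are of unlike sets of cells. An edgeR test of cell numbers called 0 classes, with 2 at an unadjusted p below 0.05. These were the neutrophil-like class at −1.15 ± 0.40 log2 (adjusted p = 0.108) and the fibroblast-like class at −0.70 ± 0.32 log2 (adjusted p = 0.227).

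**Figure D2:**
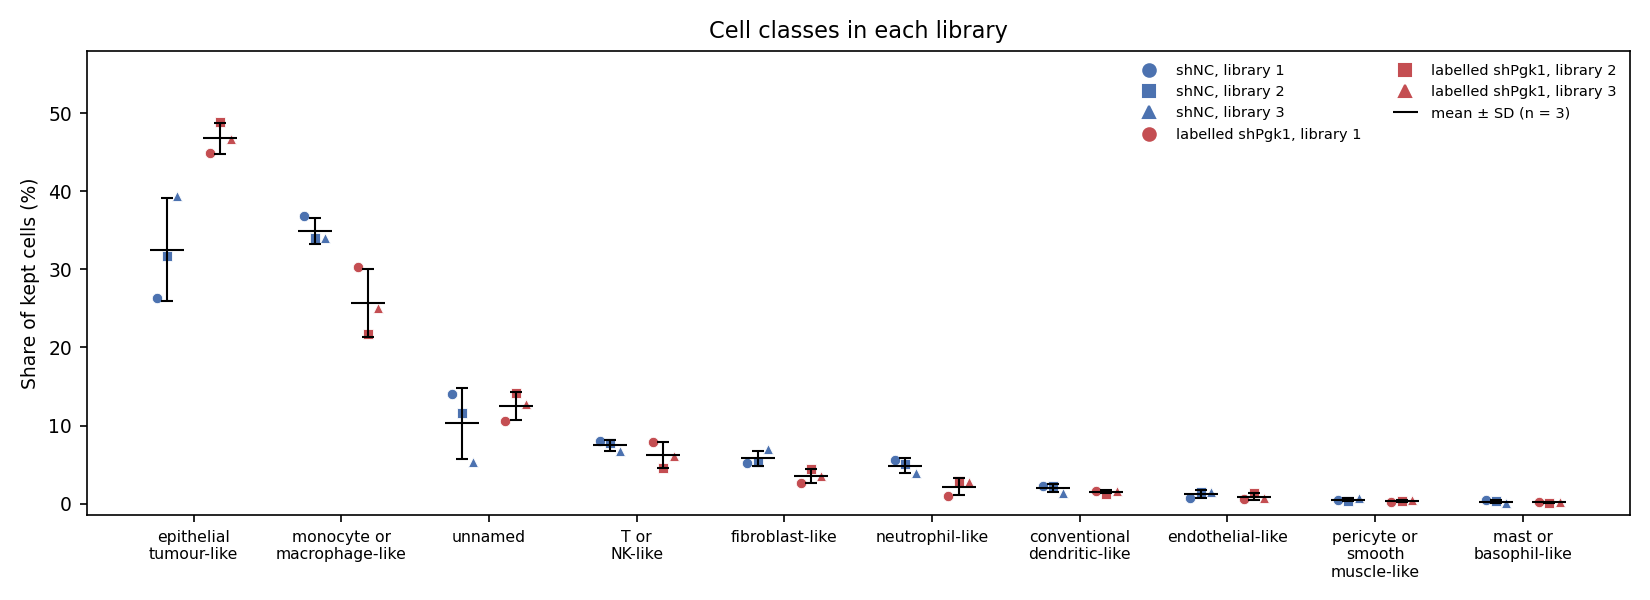
Share of kept cells (%) in each cell class for each library; symbols are libraries, and bars are the mean ± SD of 3 libraries per group. Epithelial tumour-like cells ran from 26.3 to 39.5% in shNC and from 44.9 to 48.8% in libraries labelled shPgk1, and monocyte or macrophage-like cells from 34.0 to 36.8% and from 21.8 to 30.3%.

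Over all cells, Ngp, S100a8, Hspa1a and Hspb1 were among the named falls in libraries labelled shPgk1, and Epcam, Clu and Sox9 among the named rises. Ngp, a neutrophil granule protein, went from 40.3 ± 8.09 to 5.85 ± 4.49 CPM (log2 fold −2.78 ± 0.58, adjusted p = 0.029). S100a8, a subunit of calprotectin, went from 723 ± 140 to 180 ± 108 CPM (−2.01 ± 0.50, adjusted p = 0.0393), and Hp, haptoglobin, from 51.1 ± 9.96 to 16.3 ± 1.27 CPM (−1.65 ± 0.15, adjusted p = 0.0159). Hspa1a, the inducible HSP70, went from 276 ± 99.5 to 73.6 ± 36.7 CPM (−1.91 ± 0.40, adjusted p = 0.0281). Hspb1, which encodes HSP27, went from 96.8 ± 31.6 to 34.3 ± 3.24 CPM (adjusted p = 0.0188). The other named falls were Marf1 (−1.74), Arvcf of the catenin family (−1.45), Phactr2 (−1.42), Ccdc162 (−1.41) and the calcium channel gene Cacna1d (−1.40). Epcam, an epithelial adhesion molecule, went from 182 ± 14.8 to 395 ± 78.7 CPM (1.12 ± 0.15, adjusted p = 0.0176). Clu, the secreted chaperone clusterin, went from 324 ± 44.6 to 722 ± 204 CPM (1.16 ± 0.22, adjusted p = 0.0235). The transcription factor Sox9 went from 135 ± 17.0 to 290 ± 101 CPM (adjusted p = 0.0366). The transcription factor Klf5 (1.05), the small GTPase Rab25 (1.08), the desmosome gene Perp (1.08), Fbxo2 (1.09), Tm4sf1 (1.04), Pcolce2 (1.01) and Cpe (0.99) were also higher. Ngp and S100a8 lead the neutrophil-like cluster, Clu and Perp cluster 1 and Ccdc162 cluster 4, so their sums over all cells move with the makeup of the libraries. Sox9 is among the leading genes of cluster 0, whose share of kept cells differed by −1.08 points, so that share does not go with its rise. Ngp was also lower within neutrophil-like cells (−1.42 ± 0.20), so its fall is not one of makeup alone. The share of tumour-like cells stood 14.3 points higher and that of neutrophil-like cells 2.69 points lower in libraries labelled shPgk1.

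In all, 3250 of 19518 genes passed the edgeR quasi-likelihood test over all cells (1844 higher and 1406 lower in libraries labelled shPgk1, n = 3 and 3). The count of genes past the threshold depended strongly on single libraries. It was 3 without shNC library 2, 9 without library 2 labelled shPgk1 and 3 without library 3 labelled shPgk1, all of them lower. In these fits 5293, 5492 and 5138 genes had an unadjusted p below 0.05, against 7180 with all 6 libraries. The count was 2392 without shNC library 1, 1451 without shNC library 3 and 5173 without library 1 labelled shPgk1.

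Proliferation, ribosome and respiration lists rose over all cells by camera with the preset correlation, and 0 of 27 lists passed with an estimated one (lowest adjusted p = 0.0704, 3 at an unadjusted p below 0.05). In the G1/S list 13 of 19 members rose and none fell, among them the replication genes Gins2 (0.62 ± 0.09), Tyms (0.54 ± 0.08), Mcm5 (0.51 ± 0.07) and Cdc45 (0.50 ± 0.07). Adjusted over the list alone 16 rose (camera, adjusted p = 1.94e-09, and adjusted p = 0.0704 with an estimated correlation). In the G2/M list 9 of 18 rose, and adjusted over the list alone also 9, with the mitotic genes Cdk1 at 0.58 ± 0.08 and Birc5 at 0.53 ± 0.06. This list had adjusted p = 7.76e-07, and adjusted p = 0.356 with an estimated correlation. Of 78 ribosomal protein genes 50 rose, 1 fell and 27 did not pass (72 and 1 adjusted over the list alone), Rpl12 by 0.38 ± 0.06 and Rps12 by 0.44 ± 0.07. The ribosomal list had adjusted p = 2.85e-14, and adjusted p = 0.356 with an estimated correlation. In the oxidative phosphorylation list 6 of 18 rose and 12 did not pass (9 adjusted over the list alone), led by Ndufa4 at 0.75 ± 0.12 and Ndufb9 at 0.61 ± 0.11. The respiration list had adjusted p = 0.000187, and adjusted p = 0.527 with an estimated correlation. Of 14 epithelial genes 7 rose, 1 fell and 6 did not pass (10 and 1 adjusted over the list alone), with Krt19 at 0.86 ± 0.11 and Krt18 at 0.78 ± 0.12. The epithelial list had adjusted p = 1.35e-06, and adjusted p = 0.483 with an estimated correlation, beside the 14.3 points in the share of tumour-like cells. Of 15 cholesterol synthesis genes 4 rose and 11 did not pass (6 adjusted over the list alone), among them Sqle at 0.64 ± 0.16 and Fdps at 0.54 ± 0.12. The cholesterol list had adjusted p = 0.00625, and adjusted p = 0.627 with an estimated correlation.

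The M2-like, M1-like, NF-kB target, macrophage-recruiting, p53, hypoxia and T cell effector lists fell over all cells, beside a share of monocyte or macrophage-like cells that stood 9.24 points lower. Of 17 M2-like macrophage genes 5 fell and 12 did not pass (6 fell adjusted over the list alone). They included Chil3 (−2.03 ± 0.25, at 3.34 CPM in shNC and 0.817 CPM in libraries labelled shPgk1), arginase Arg1 (−0.83 ± 0.18), Folr2 (−0.63 ± 0.13) and the mannose receptor Mrc1 (−0.37 ± 0.10). The M2-like list had adjusted p = 0.000751, and adjusted p = 0.356 with an estimated correlation. Of 15 M1-like genes 3 fell and 12 did not pass (5 adjusted over the list alone), Il6 at −1.34 ± 0.20, Cd80 at −0.46 ± 0.07 and Il12a at −1.39 ± 0.39. The M1-like list had adjusted p = 0.0019, and adjusted p = 0.545 with an estimated correlation. Of 29 NF-kB target genes 3 fell, Il6, the apoptosis inhibitor Birc3 (−0.61 ± 0.14) and the adhesion molecule Icam1 (−0.56 ± 0.14), Lcn2 rose (0.44 ± 0.12) and 25 did not pass. Adjusted over the list alone 2 fell and none rose (adjusted p = 0.0214, and adjusted p = 0.576 with an estimated correlation). Of 23 macrophage-recruiting and polarising factors 6 fell, 2 rose and 15 did not pass (8 and 3 adjusted over the list alone). Among them were Vegfa at −0.81 ± 0.13, Tgfb1 at −0.52 ± 0.09 and Il13, at only 3.71 CPM in shNC, at −3.28 ± 0.60. The recruiting factors had adjusted p = 0.0214, and adjusted p = 0.527 with an estimated correlation. Of 16 p53 target genes 6 fell and 10 did not pass, 6 also adjusted over the list alone, including Cdkn1a (−0.53 ± 0.11) and Sesn2 (−0.73 ± 0.12). The p53 list had adjusted p = 0.00424, and adjusted p = 0.356 with an estimated correlation. Of 16 hypoxia genes 4 fell, 1 rose and 11 did not pass (6 and 1 adjusted over the list alone). Adrenomedullin Adm (−1.31 ± 0.25), Vegfa and Egln3 (−0.61 ± 0.12) were lower and carbonic anhydrase Car9 (0.72 ± 0.10) was higher. The hypoxia list had adjusted p = 0.0146, and adjusted p = 0.527 with an estimated correlation. Of 12 T cell effector and exhaustion genes 0 passed over all genes in edgeR (4 at an unadjusted p below 0.05, 3 by DESeq2) and 3 fell adjusted over the list alone. Havcr2 stood at −0.50 ± 0.14 (list adjusted p = 0.0319, and adjusted p = 0.667 with an estimated correlation). Single libraries decided 4 of these list calls over all cells. The hypoxia list lost it without shNC library 3 (adjusted p = 0.074), and the NF-kB list without shNC library 1 or library 1 labelled shPgk1 (0.158 and 0.221). The recruiting factors lost it without shNC library 3 or library 1 labelled shPgk1 (0.0758 and 0.333), and the T cell list without shNC library 1 or library 3 labelled shPgk1 (0.158 and 0.164).

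The remaining 14 lists did not pass over all cells, with adjusted p between 0.0758 and 0.99. Of 17 glycolysis genes other than Pgk1 2 rose, 3 fell and 12 did not pass (2 and 4 adjusted over the list alone; camera, adjusted p = 0.935). The aldolase Aldoc (0.54 ± 0.07) and the enolase Eno1 (0.39 ± 0.08) were higher, and the transporters Slc16a3 (−0.70 ± 0.11) and Slc2a1 (−0.42 ± 0.11) were lower. In the serine and one-carbon list 2 of 8 rose, among them the serine synthesis enzyme Phgdh (0.69 ± 0.09), and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.117). In the pentose phosphate list 3 of 7 rose, led by Rpia at 0.54 ± 0.08 (3 adjusted over the list alone; adjusted p = 0.0976). In the integrated stress response 2 of 11 fell, Sesn2 among them (3 adjusted over the list alone; adjusted p = 0.405). In the unfolded protein response the chaperone Hspa5 alone of 12 rose in edgeR, by 0.27 ± 0.07 (adjusted p = 0.332), and among NF-kB pathway components the kinase Ikbkb alone of 8 fell in edgeR, by 0.26 ± 0.07 (adjusted p = 0.644). Neither single gene passed when adjusted over its list alone. DESeq2 called 2 and 0 members of these lists. Of 17 interferon-stimulated genes 3 rose, including Bst2 (0.37 ± 0.09) and Usp18 (0.53 ± 0.14), and Oasl1 fell by 0.89 ± 0.23 (3 and 1 adjusted over the list alone; adjusted p = 0.889). Of 11 NRF2 and ferroptosis defence genes 3 rose, among them the glutathione genes Gsr (0.47 ± 0.07) and Gclm (0.49 ± 0.10). Adjusted over the list alone 4 rose and 2 fell (adjusted p = 0.476). Of 13 mesenchymal genes S100a4 rose (0.71 ± 0.13) and 2 fell (2 and 4 adjusted over the list alone; adjusted p = 0.466). Of 15 immediate early and dissociation genes Fos rose (0.49 ± 0.10) and 4 fell, Hspa1a among them (1 and 5 adjusted over the list alone; adjusted p = 0.889). Of 13 mitochondrially encoded genes 2 rose, with mt-Nd1 at 0.36 ± 0.09 (2 adjusted over the list alone; adjusted p = 0.0758). Of 11 MHC class I, 7 MHC class II and 12 checkpoint ligand genes 0 passed in edgeR by either adjustment (camera, adjusted p = 0.99, 0.369 and 0.935). There were 0, 0 and 3 at an unadjusted p below 0.05 and 0, 0 and 3 called by DESeq2. Camera's direction was up while the median and mean fold lay below 0 for glycolysis, checkpoint ligands and NRF2 genes. It was up with a mean of −0.03 for MHC class I, and it was down with a median of 0.04 for immediate early genes.

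Within epithelial tumour-like cells the largest differences were falls. The cytidine deaminase Apobec1 went from 119 ± 35.9 CPM in shNC to 40.6 ± 6.73 CPM in libraries labelled shPgk1 (log2 fold −1.55 ± 0.23, adjusted p = 0.0236). The cytochrome oxidase translation factor Taco1 went from 56.5 ± 15.1 to 21.6 ± 3.96 CPM (−1.39 ± 0.22, adjusted p = 0.0236), and Spata7 from 891 ± 228 to 348 ± 28.7 CPM (−1.36 ± 0.18, adjusted p = 0.014). The ciliary gene Cfap44 (−1.36), the rhomboid protease Rhbdd1 (−1.32), the chromatin reader Phf21a (−1.25), Rhd (−1.23) and the transporter-like Svopl (−1.19) were lower as well. So were Marf1 (−1.28) and the chemokine Ccl6 (−1.11), both near the free-RNA level in these cells. Rises were smaller. Yrdc, which acts in tRNA modification, went from 25.6 ± 3.98 to 47.3 ± 7.11 CPM (0.89 ± 0.14, adjusted p = 0.0207). It was followed by Chic2 (0.78), Nsmce4a of the SMC5/6 complex (0.73), Zfand5 (0.72), Cdv3 (0.71), the ubiquitin-conjugating enzyme Ube2s (0.70), the HSP90 co-chaperone Ahsa2 (0.70), Klhdc2 (0.69), Clu (0.68) and Lypd3 (0.68).

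In epithelial tumour-like cells 1422 of 16314 genes passed (574 higher and 848 lower in libraries labelled shPgk1; edgeR quasi-likelihood, n = 3 and 3), and 308 of the falls were of genes near the free-RNA level. On average different clusters held most of the class in the groups, and these clusters differed in depth and quality. Cluster 0 held 57.6 ± 7.37% of it in shNC and 38.4 ± 2.30% in libraries labelled shPgk1, and cluster 1 held 42.4 ± 7.37% and 61.6 ± 2.30%. In shNC library 1 cluster 1 held the larger part of the class (50.4%, with 49.6% in cluster 0). Of all kept cells, cluster 0 made up 19.0 ± 6.13% in shNC and 17.9 ± 1.23% in libraries labelled shPgk1. Cluster 1 made up 13.5 ± 0.583% and 28.9 ± 1.72% of them. The median cell of cluster 0 had 8926 UMIs, 1.92% of them mitochondrial and 11.8% from ribosomal-RNA-like genes, against 15028.5 UMIs, 0.80% and 7.20% in cluster 1. Spata7 is among the leading genes of cluster 0 and Clu among those of cluster 1, so their folds over the class move with these shares. Within cluster 0, Spata7 differed by −1.06 ± 0.15 and Apobec1 by −1.23 ± 0.19, and within cluster 1 by −0.71 ± 0.10 and −0.90 ± 0.12, all past the threshold, as was Ccl6 in both. Taco1, Rhbdd1, Phf21a and Rhd passed in cluster 0 and not in cluster 1 (−0.45, −0.55, −0.48 and −0.60). Cfap44 and Svopl passed in cluster 1 and not in cluster 0 (−1.01 and −0.80), and Marf1 in neither (adjusted p = 0.055 and 0.0854). Of the named rises Yrdc passed in cluster 0 (0.90 ± 0.16, adjusted p = 0.024) and not in cluster 1 (0.62 ± 0.15, adjusted p = 0.086). Zfand5 passed in cluster 0 alone, Klhdc2 in cluster 1 alone and the others in neither, with Clu at 0.59 and 0.36. Of the 574 rises 7 passed in cluster 0, 17 in cluster 1 and 0 in both, and of the 848 falls 98, 121 and 32. This was edgeR in each cluster, with 2856 and 2637 genes at an unadjusted p below 0.05 and 5696 over the class. The count was 17 without shNC library 2, 169 without shNC library 3 and 4140 without shNC library 1, where the balance turned (2281 higher and 1859 lower). It was 2260, 74 and 5 without libraries 1, 2 and 3 labelled shPgk1. Without shNC library 2, 4065 genes had an unadjusted p below 0.05. Without libraries 2 and 3 labelled shPgk1, 4229 and 3549 did. The count past the threshold was 259 with the estimated free RNA subtracted (15.8% higher), 3006 with DESeq2 (58.2% higher, against 40.4%) and 2767 with no gene filter (58.8% higher).

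**Figure D3:**
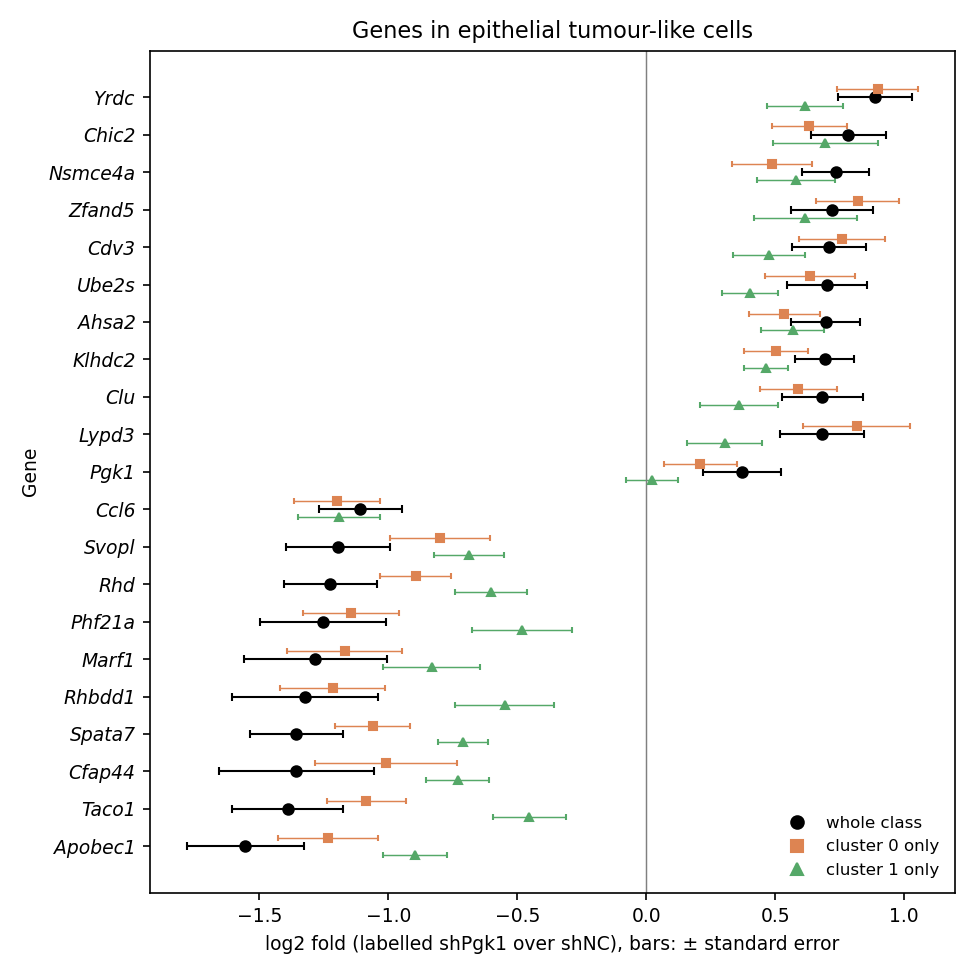
Log2 fold (libraries labelled shPgk1 over shNC) of Pgk1 and the named genes in epithelial tumour-like cells; circles are the whole class, squares cluster 0 alone and triangles cluster 1 alone, with bars of ± 1 standard error from edgeR. Apobec1 lies at −1.55 in the class, −1.23 in cluster 0 and −0.90 in cluster 1, and Yrdc at 0.89, 0.90 and 0.62.

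The lists of ribosomal protein, respiration and G1/S genes rose within epithelial tumour-like cells by camera with the preset correlation, and none of them with an estimated one. Of 78 ribosomal protein genes 2 rose over all genes (Rpl10 at 0.48 ± 0.12 and Rpl35 at 0.41 ± 0.11) while 67 rose and 1 fell adjusted over the list alone. The ribosomal list had the lowest p (camera, adjusted p = 1.41e-16, and adjusted p = 0.583 with an estimated correlation). It passed in cluster 0 alone (adjusted p = 3.72e-10) and not in cluster 1 alone (adjusted p = 0.154), where Rpl10 and Rpl35 stood at 0.14 and 0.09. Of 19 G1/S genes 8 rose and 11 did not pass (14 rose and 1 fell adjusted over the list alone), with Rrm2 at 0.54 ± 0.12 and Pcna at 0.46 ± 0.10. Within clusters 0 and 1 Rrm2 stood at 0.24 and 0.43 and Pcna at 0.26 and 0.30, past the threshold in neither. The G1/S list had adjusted p = 2.23e-06, and adjusted p = 0.583 with an estimated correlation, and it passed in each cluster (adjusted p = 0.025 and 4.86e-08). Of 18 oxidative phosphorylation genes 1 rose, Ndufa4 by 0.62 ± 0.14, and 15 adjusted over the list alone. Respiration had adjusted p = 3.19e-06, and adjusted p = 0.583 with an estimated correlation. It passed in cluster 0 (adjusted p = 0.000991) and not in cluster 1 (adjusted p = 0.13), with Ndufa4 at 0.52 and 0.32, past the threshold in neither. The unfolded protein response list also rose, with 0 of 12 members past the threshold in edgeR by either adjustment (4 at an unadjusted p below 0.05, 3 by DESeq2) and Dnajb9 at 0.42 ± 0.12 (adjusted p = 0.00612, and adjusted p = 0.583 with an estimated correlation). Without genes near the free-RNA level that list had adjusted p = 0.0525, and within clusters 0 and 1 it had 0.0745 and 0.298. Weaker calls were G2/M genes (2 of 18 rose, Birc5 and Ube2c, and 5 adjusted over the list alone), cholesterol synthesis (1 of 15 rose, and 0 adjusted over the list alone in edgeR, with 6 at an unadjusted p below 0.05 and 5 by DESeq2) and the pentose phosphate pathway (0 of 7 in edgeR by either adjustment, 3 at an unadjusted p below 0.05, 2 by DESeq2). Each had adjusted p = 0.0412, and adjusted p = 0.583 with an estimated correlation. The G2/M call was lost without shNC library 1, shNC library 3 or library 1 labelled shPgk1 (adjusted p = 0.1, 0.0733 and 0.241). The cholesterol call was lost without shNC library 1, shNC library 3 or library 3 labelled shPgk1 (0.249, 0.0535 and 0.109). The pentose call was lost without shNC library 2 or 3 or library 1 or 3 labelled shPgk1 (0.0544, 0.0937, 0.0779 and 0.0502) in epithelial tumour-like cells. Without genes near the free-RNA level they had adjusted p = 0.143, 0.106 and 0.106 in turn. After free-RNA subtraction the G2/M and cholesterol lists had 0.428 and 0.174. Within cluster 0 the G2/M, cholesterol and pentose lists had adjusted p = 0.937, 0.15 and 0.352, and within cluster 1 the pentose list had 0.733. Birc5 and Ube2c passed in neither cluster.

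NF-kB target genes and both macrophage lists fell within epithelial tumour-like cells by camera with the preset correlation, and many of their members were near the free-RNA level. Of 29 NF-kB target genes 5 fell and 24 did not pass (9 adjusted over the list alone). Birc3 (−0.77 ± 0.11), Icam1 (−0.73 ± 0.13), Il6 (−1.59 ± 0.29, at 3.78 CPM in shNC) and the chemokine Cxcl2 (−0.61 ± 0.13) were all near the free-RNA level. In all, 13 of the 29 were near it (adjusted p = 0.000951, and adjusted p = 0.583 with an estimated correlation). Within clusters 0 and 1 Il6 passed in both, Birc3 (−0.64 and −0.67) and Cxcl2 (−0.56 and −0.74) in cluster 1 alone and Icam1 (−0.64 and −0.74) in neither. With the estimated free RNA subtracted this list had adjusted p = 0.174, and without genes near the free-RNA level 0.262. Of 15 M1-like genes 4 fell and 11 did not pass (7 adjusted over the list alone). Nitric oxide synthase Nos2 went from 119 ± 18.0 to 63.4 ± 10.9 CPM (−0.90 ± 0.15; −0.71 and −0.78 within clusters 0 and 1, past the threshold in neither), above the free-RNA level, and 9 members were near it (adjusted p = 4.4e-05, adjusted p = 0.583 with an estimated correlation, and adjusted p = 0.0525 without genes near the free-RNA level). Of 17 M2-like genes 4 fell and 13 did not pass (8 adjusted over the list alone). All 17 were near the free-RNA level (adjusted p = 4.4e-05, adjusted p = 0.501 with an estimated correlation, and adjusted p = 0.428 after subtraction), beside the lower share of monocyte or macrophage-like cells. Glycolysis had no call. Aldoc (0.59 ± 0.12), Eno1 (0.56 ± 0.13) and the lactate dehydrogenase gene Ldha (0.50 ± 0.13) rose, Slc16a3, near the free-RNA level, fell by 0.94 ± 0.16 and 13 of 17 did not pass (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.0522). Within clusters 0 and 1 Eno1 stood at 0.34 and 0.24 and Ldha at 0.25 and 0.19, and Aldoc, Eno1 and Ldha passed in neither. Among 22 macrophage-recruiting factors osteopontin, Spp1, rose (0.57 ± 0.11) and 18 did not pass. Il6, Ccl7 (−0.86 ± 0.18) and Vegfa (−0.46 ± 0.12), near the free-RNA level, fell (2 rose and 6 fell adjusted over the list alone; adjusted p = 0.104). Spp1 and Vegfa passed in neither cluster, and Ccl7 in cluster 1 alone.

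Monocyte or macrophage-like cells showed 97 falls and 15 rises among 15613 genes (edgeR quasi-likelihood, n = 3 and 3). Arvcf, of the catenin family, went from 113 ± 8.01 CPM in shNC to 49.4 ± 9.47 CPM in libraries labelled shPgk1 (log2 fold −1.20 ± 0.13, adjusted p = 0.00901) and Spata7 from 264 ± 34.8 to 123 ± 12.4 CPM (−1.10 ± 0.11, adjusted p = 0.00364). Cfap44 (−1.23 ± 0.15), the actin regulator Phactr2 (−1.15 ± 0.17) and Svopl (−1.14 ± 0.13) were the other named falls. Among rises, Pclaf, a PCNA-associated factor, went from 53.4 ± 4.98 to 78.8 ± 8.43 CPM (0.56 ± 0.10, adjusted p = 0.0499) and Chordc1 from 21.3 ± 2.00 to 31.0 ± 0.391 CPM (0.54 ± 0.09, adjusted p = 0.0347). Epcam (0.87 ± 0.11), Nop58 (0.64 ± 0.12) and Cks1b (0.59 ± 0.10) were near the free-RNA level, as were 18 of all calls. Cluster 5 held a mean of 57.1% of the class in shNC and 66.5% in libraries labelled shPgk1, and most of it in each library but shNC library 1 (47.4%, with 49.6% in cluster 4). Of the 97 falls 55 passed in cluster 4, 51 in cluster 5 and 27 in both, and of the 15 rises 4, 5 and 2. Of the genes named here Arvcf, Cfap44, Epcam and Cks1b passed in both, and Spata7, Svopl and Chordc1 in cluster 4 alone (−0.96, −0.96 and 0.40 in cluster 5). Phactr2 (−1.29 and −0.93), Pclaf (0.55 and 0.43) and Nop58 (0.65 and 0.58) passed in neither. The count was 41 without shNC library 2, and 499, 40 and 15 without libraries 1, 2 and 3 labelled shPgk1. It was 65 with the estimated free RNA subtracted, 607 with DESeq2 (25.9% higher, against 13.4%) and 576 with no gene filter (28.3% higher).

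The series title names M2-like macrophages, and the M2-like list did not pass within monocyte or macrophage-like cells. Of its 17 members 0 passed in edgeR over all genes (2 at an unadjusted p below 0.05, 2 by DESeq2) and 2 fell adjusted over the list alone. These were Chil3 (6.28 ± 0.931 CPM in shNC and 2.45 ± 1.12 CPM in libraries labelled shPgk1, −1.39 ± 0.29, adjusted p = 0.0758) and Arg1, which leads clusters 4 and 5 (1052 ± 58.8 and 801 ± 82.9 CPM, −0.39 ± 0.09, adjusted p = 0.0842). Il10 stood at 0.65 ± 0.39 and Mgl2 at 0.57 ± 0.34, with a list median of −0.02 (camera, adjusted p = 0.631). The M1-like list stood at a median of −0.24 with 0 of 15 members past the threshold in edgeR by either adjustment (1 at an unadjusted p below 0.05, 0 by DESeq2; adjusted p = 0.218). Its members included Nos2 at −1.04 ± 0.56 and Il12a at −0.97 ± 0.36. NF-kB target genes (0 of 29 in edgeR by either adjustment, adjusted p = 0.627), glycolysis (0 of 17 by either adjustment, adjusted p = 0.179) and recruiting factors (0 of 21, 1 fell adjusted over the list alone, adjusted p = 0.463) did not pass either. At an unadjusted p below 0.05 these held 0, 3 and 4 genes, and by DESeq2 0, 2 and 3. For the NF-kB targets camera's direction was up with a mean fold of −0.02.

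Replication, mitosis and chaperone lists rose in monocyte or macrophage-like cells, and the hypoxia list fell, by camera with the preset correlation. With an estimated correlation 0 of 27 lists passed (lowest adjusted p = 0.635, 0 at an unadjusted p below 0.05). Over all genes 0 members of the G1/S, G2/M, unfolded protein response and hypoxia lists passed in edgeR (13, 11, 9 and 8 at an unadjusted p below 0.05; 1, 3, 1 and 5 by DESeq2). Adjusted over the list alone, 13 of 19 G1/S genes rose (Rrm1 at 0.47 ± 0.09) and 7 of 18 G2/M genes rose (Mki67 at 0.44 ± 0.11). Each of these lists had adjusted p = 2.21e-07, and adjusted p = 0.635 with an estimated correlation. By the same count 7 of 12 unfolded protein response genes rose (the chaperone Hspa5 at 0.33 ± 0.08; adjusted p = 0.000128) and 7 of 16 hypoxia genes fell (Adm at −0.92 ± 0.18, Vegfa at −0.51 ± 0.11; adjusted p = 1.6e-06). Both had adjusted p = 0.635 with an estimated correlation. Epithelial genes also rose as a list, with all 12 members near the free-RNA level, 1 past the threshold over all genes and 4 adjusted over the list alone. That list had adjusted p = 5.81e-06, and adjusted p = 0.635 with an estimated correlation, beside the higher share of tumour-like cells. After free-RNA subtraction the direction turned (adjusted p = 0.869). The T cell list fell with 8 of 12 members near the free-RNA level, 0 members past the threshold over all genes in edgeR (3 at an unadjusted p below 0.05, 1 by DESeq2) and 1 adjusted over the list alone. The T cell list had adjusted p = 0.0119, and adjusted p = 0.635 with an estimated correlation. That call was lost without shNC library 1 (adjusted p = 0.0738) or library 3 labelled shPgk1 (adjusted p = 0.103) in monocyte or macrophage-like cells.

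Tumour-like and macrophage-like cells shared some falls. Of 14919 genes tested in both classes, 789 fell in epithelial tumour-like and 95 in monocyte or macrophage-like cells, with 59 in common where independent lists would share 5.02. Another 560 and 14 rose, with 7 in common against 0.525. Spata7, Cfap44 and Svopl were among the named falls of both classes. Both comparisons used the same 6 libraries, so part of the overlap can come from the shared libraries and from free RNA. A test of the difference between the classes called 403 of 16982 genes (49 with the larger fold in tumour-like cells and 354 with the smaller; edgeR quasi-likelihood interaction). Among them were Ccl7 (−1.37 ± 0.16) and the protease inhibitor Slpi (1.29 ± 0.16). The count was 1048 without shNC library 1, where the balance turned (622 larger and 426 smaller), 175 and 76 without shNC libraries 2 and 3, and 791, 135 and 15 without libraries 1, 2 and 3 labelled shPgk1. It was 1 with the estimated free RNA subtracted, and 1274 with no gene filter, where the balance also turned (742 larger and 532 smaller). For Pgk1 the difference between the classes was 0.33 ± 0.16 (adjusted p = 0.313), and 0.45 with no gene filter (adjusted p = 0.0377).

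The smaller classes gave few calls. In T or NK-like cells 19 of 11808 genes passed, 18 of them lower in libraries labelled shPgk1 and 15 of these near the free-RNA level. The named falls were all near it: Crabp1 (−1.51), Ccl6 (−1.23 ± 0.15, adjusted p = 0.00431), Spata7 (−1.08), Apobec1 (−1.07) and Oasl1 (−0.99). The calcium-binding S100a4 rose from 966 ± 110 to 1612 ± 125 CPM (0.74 ± 0.11, adjusted p = 0.017). In T or NK-like cells the call of S100a4 ended without shNC library 1 or 2 or library 2 labelled shPgk1 (adjusted p = 0.0574, 0.124 and 0.159) and after free-RNA subtraction (0.72 ± 0.13, adjusted p = 0.221). In neutrophil-like cells 7 of 5299 genes passed. Ngp went from 3631 ± 273 to 1347 ± 495 CPM (−1.42 ± 0.20, adjusted p = 0.0144) and Ccl6 from 742 ± 123 to 383 ± 44.4 CPM (−0.93 ± 0.17, adjusted p = 0.0337), beside a median of 0.48 over 11 mitochondrially encoded genes (camera, adjusted p = 4.81e-11, and adjusted p = 0.338 with an estimated correlation). Ccl7 (−1.62) and the higher Areg (1.74), Krt14 (1.69), Sox9 (1.23) and Krt8 (1.07) were near the free-RNA level. In fibroblast-like cells 4 of 12247 genes passed, all lower. Slpi went from 144 ± 6.93 to 73.5 ± 7.84 CPM (−0.98 ± 0.11, adjusted p = 0.0287), with Arg1 (−1.27) and the interferon-induced Oasl1 (−1.11) near the free-RNA level. In conventional dendritic-like cells 3 of 8831 and in endothelial-like cells 5 of 8977 genes passed, all lower. Col1a1 (−1.30 and −1.04), and in endothelial-like cells Marf1 (−1.59), Arg1 (−1.56) and Apoe (−0.89), were near the free-RNA level. After subtraction of the estimated free RNA the folds of Col1a1 and Apoe in endothelial-like cells were 1.89 ± 1.23 and 0.90 ± 1.79, above 0 and not past the threshold (edgeR, adjusted p = 0.995 for each). With the estimated free RNA subtracted the counts were 1, 0, 0, 1 and 0 in T or NK-like, neutrophil-like, fibroblast-like, dendritic-like and endothelial-like cells (edgeR; 681, 165, 662, 496 and 325 at an unadjusted p below 0.05). With DESeq2 on the deposited counts they were 62, 13, 44, 26 and 8. Without shNC libraries 1, 2 and 3 and libraries 1, 2 and 3 labelled shPgk1 in turn, the T or NK-like count was 37, 12, 36, 59, 10 and 13. In the same order the neutrophil-like count was 9, 5, 10, 22, 14 and 1 and the fibroblast-like count 11, 1, 5, 7, 0 and 0. The dendritic-like count was 2, 1, 5, 26, 1 and 2 and the endothelial-like count 14, 4, 6, 5, 0 and 0. For the last 2 left-out libraries 914 and 785 fibroblast-like and 526 and 497 endothelial-like genes had an unadjusted p below 0.05 in edgeR.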

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

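No test of an explanation is reported in this part, and the genes below follow the fixed order of size among those past the threshold. Groups of 3 libraries were not searched for single libraries far from the others.

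The difference between libraries labelled shPgk1 and shNC depended on the class for 403 genes (edgeR quasi-likelihood interaction, epithelial tumour-like against monocyte or macrophage-like cells). The folds of each class and the differences below come from separate fits, so the folds need not subtract to the difference. The chemokine Ccl7 had a log2 fold of −0.86 ± 0.18 in tumour-like cells, where it was near the free-RNA level, and of 0.44 ± 0.14 in macrophage-like cells, a difference of −1.37 (adjusted p = 0.000977). The chemokine Ccl2 differed by −1.17 between the classes, with −0.68 (near the free-RNA level) and 0.37. Taco1 differed by −1.09, with −1.39 and −0.32, the second near the free-RNA level. Arhgap30 differed by −1.03, with −0.95 (near the free-RNA level) and 0.02, and BC028528 by −1.01, with −1.39 (near the free-RNA level) and −0.42. In the other direction, the protease inhibitor Slpi differed by 1.29 (0.55 in tumour-like and −0.83 in macrophage-like cells) and Msantd3 by 1.02 (−0.17, near the free-RNA level, and −1.23). Polr2l differed by 1.00 (0.08 and −0.97), the inducible heat shock gene Hspa1b by 0.95 (−0.72 and −1.68) and the matrix glycoprotein gene Thbs1 by 0.93 (0.08 and −0.88). With the estimated free RNA subtracted 1 gene passed this test.

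Some cells entered no comparison of genes within a class. Cluster 2 held 4203 cells led by Zfp791, Taco1 and mitochondrial genes such as mt-Nd5, with a median of 3717 UMIs and 25.2% of them from the ribosomal-RNA-like genes Gm42418 and AY036118. Cluster 15 held 369 cells led by Gm10801 and by the neuronal adhesion genes Nrxn3 and Cntnap2, with a median of 2302 UMIs. Cluster 13 held 203 cells that carried markers of both plasmacytoid dendritic (Siglech) and B cells (Cd79a, Ighm). Mast or basophil-like cells (cluster 6) numbered 98 and pericyte or smooth muscle-like cells (cluster 14) numbered 177.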

How the results depend on the processing

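The settings with free RNA subtracted, with the ribosomal-RNA-like genes left out, with genes near the free-RNA level left out, with unnamed clusters left out and with cells of single clusters were chosen after the data were seen, and the others before. The cause of each change below was not tested, except that fewer libraries, fewer cells or fewer genes entered where the setting says so.

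Over 1 setting at a time, 2348 pairs of a named gene other than Pgk1 and a setting held their direction and side of the threshold, 1006 held the direction and lost the threshold, and 2 turned. With relative log expression normalization, a mitochondrial limit of 10%, genes listed in all 6 libraries only and the ribosomal-RNA-like genes left out, each count of genes stayed within 1.5 times its value. The minimum of UMIs per cell left out no barcode, since the shallowest barcode already lay above it. No minimum above the shallowest barcode was tested, so dependence of the results on such a limit is not known.

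DESeq2 called 62 genes in T or NK-like, 26 in dendritic-like, 8 in endothelial-like, 3006 in epithelial tumour-like, 44 in fibroblast-like, 607 in monocyte or macrophage-like and 13 in neutrophil-like cells, and turned Pgk1 in monocyte or macrophage-like cells to 0.0079 log2. Without a gene filter the counts were 355, 127, 115, 2767, 359, 576 and 72 in the same order, 1274 genes depended on the class, Pgk1 in neutrophil-like cells turned to −0.035 and the class difference of Pgk1 became 0.4548 and passed. With all deposited barcodes the counts were 2 in fibroblast-like and 4 in neutrophil-like cells and Pgk1 in monocyte or macrophage-like cells was 0.0063, and with predicted doublets kept they were 2, 4 and 0.0064. Thinned to the smallest library, endothelial-like cells gave 2 and neutrophil-like cells 3 genes. Cluster 0 alone gave 112 genes and 9 lists and cluster 1 alone 173 genes and 10 lists in epithelial tumour-like cells.

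With the estimated free RNA subtracted, the counts of genes were 1 in T or NK-like, 1 in dendritic-like, 0 in endothelial-like, 259 in epithelial tumour-like, 0 in fibroblast-like, 65 in monocyte or macrophage-like and 0 in neutrophil-like cells (edgeR, with 325, 662 and 165 genes at an unadjusted p below 0.05 where the count was 0), and 1 gene depended on the class. Lists numbered 5 in T or NK-like, 6 in endothelial-like and 10 in monocyte or macrophage-like cells. Lists that turned were MHC class II in T or NK-like (adjusted p = 0.108, up) and fibroblast-like cells (0.665, up), M2-like genes in fibroblast-like cells (0.199, up) and epithelial genes in fibroblast-like and monocyte or macrophage-like cells (down, signed adjusted p of −0.120 and −0.869). In endothelial-like cells Col1a1 turned to 1.89 and Apoe to 0.90. Without genes near the free-RNA level the counts were 3 in T or NK-like, 1 in endothelial-like, 1 in fibroblast-like and 2 in neutrophil-like cells, 88 genes depended on the class, and lists numbered 8 in endothelial-like, 4 in epithelial tumour-like and 1 in neutrophil-like cells.

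With an estimated correlation 0 lists passed in camera in each of the 8 comparisons. At an unadjusted p below 0.05 there were 3 in all cells, 3 in T or NK-like, 1 in dendritic-like, 4 in endothelial-like, 1 in epithelial tumour-like, 2 in fibroblast-like, 0 in monocyte or macrophage-like and 3 in neutrophil-like cells. By fry for a shift of a list in 1 direction 6, 1, 1, 0, 2, 0, 0 and 0 lists passed in the same order. By fry for changes of members in either direction 22, 8, 0, 1, 20, 3, 3 and 0 passed.

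The numbers of the labels gave no clear pairing of the libraries. Same-numbered libraries correlated between −0.298 and 0.281, and in no comparison did each library correlate best with its own number. In all cells and in endothelial-like cells 2 shNC libraries did. With 3 libraries per group this check cannot exclude a pairing. With the replicate block 2627 genes passed over all cells (44.8% higher, against 56.7%), 11 in dendritic-like, 19 in endothelial-like, 557 in epithelial tumour-like (11.7% higher, against 40.4%), 26 in fibroblast-like, 47 in monocyte or macrophage-like and 54 in neutrophil-like cells, and the pentose phosphate list in epithelial tumour-like cells lost its call (adjusted p = 0.051).

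Leaving out each library in turn gave 3 to 5173 genes over all cells, 10 to 59 in T or NK-like, 1 to 26 in dendritic-like, 0 to 14 in endothelial-like, 5 to 4140 in epithelial tumour-like, 0 to 11 in fibroblast-like, 15 to 499 in monocyte or macrophage-like and 1 to 22 in neutrophil-like cells, and 15 to 1048 that depended on the class. The 0 counts came without library 2 or 3 labelled shPgk1 (edgeR, 526 and 497 endothelial-like and 914 and 785 fibroblast-like genes at an unadjusted p below 0.05). Lists numbered 11 to 14 over all cells and 8 to 11, 5 to 8, 9 to 14, 7 to 13, 8 to 17, 6 to 16 and 2 to 6 in the classes in that order. Pgk1 ranged from 0.019 to 0.134 over all cells, 0.2495 to 0.514 in epithelial tumour-like, −0.111 to 0.092 in T or NK-like, −0.013 to 0.135 in dendritic-like, −0.029 to 0.241 in endothelial-like, −0.162 to −0.033 in fibroblast-like, −0.053 to 0.037 in monocyte or macrophage-like and −0.128 to 0.169 in neutrophil-like cells, and its class difference from 0.210 to 0.473. It changed sign without library 1 labelled shPgk1 in T or NK-like (−0.111), without library 2 labelled shPgk1 in dendritic-like (−0.013), without library 3 labelled shPgk1 in endothelial-like cells (−0.029, and also below 0 without shNC library 2), without shNC library 2 or library 3 labelled shPgk1 in monocyte or macrophage-like cells (0.037 and 0.022), and without shNC library 2 in neutrophil-like cells (−0.128). Share differences ranged from 11.2 to 17.8 points for epithelial tumour-like, −11.6 to −7.28 for monocyte or macrophage-like, −3.19 to −2.06 for neutrophil-like and −2.69 to −1.69 for fibroblast-like cells. With the unnamed clusters 2 and 15 left out, the share of epithelial tumour-like cells differed by 17.5 points.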

Other observations

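The tests on Pgk1, the levels of Gm14015 across classes, the tests on Xist and the counts over splits of the libraries were written after their results were seen. The tests of gene lists and the comparison of shallow and deep cells for Gm14015 were set before.

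In the smaller classes some fixed lists passed although few single genes did. In fibroblast-like cells NF-kB target genes were lower in libraries labelled shPgk1 (camera, adjusted p = 1.13e-07, and adjusted p = 0.352 with an estimated correlation), with the inhibitor Nfkbia at −0.35 ± 0.10 and the chemokine Cxcl1 at −0.50. Of its 29 members 0 passed in edgeR by either adjustment (9 at an unadjusted p below 0.05, 1 by DESeq2), and 8 were near the free-RNA level. Macrophage lists were lower beside it there, M1-like at a median of −0.67 (8 of 13 near the free-RNA level), MHC class II at −0.50 (7 of 7) and M2-like at −0.38 (12 of 13), with adjusted p = 4.02e-05, 0.00364 and 1.75e-05, and adjusted p = 0.53, 0.622 and 0.236 with an estimated correlation. After free-RNA subtraction the MHC class II and M2-like lists turned upward and did not pass. G1/S genes were higher in fibroblast-like cells (adjusted p = 3.47e-07, and adjusted p = 0.352 with an estimated correlation), with the ribonucleotide reductase subunit Rrm2 at 0.69 ± 0.22 and 0 of 19 members past the threshold in edgeR by either adjustment (5 at an unadjusted p below 0.05, 0 by DESeq2). The epithelial list was higher beside it, with 4 of 11 members at an unadjusted p below 0.05 and 0 called in edgeR. After free-RNA subtraction the epithelial list turned downward. In T or NK-like cells the hypoxia list was lower (adjusted p = 7.29e-05, and adjusted p = 0.326 with an estimated correlation), with 2 of 16 members falling when adjusted over the list alone and 0 over all genes in edgeR (7 at an unadjusted p below 0.05, 0 by DESeq2). Of these 16 members 5 were near the free-RNA level. NF-kB target genes were lower there too (adjusted p = 4.71e-06, and adjusted p = 0.326 with an estimated correlation), with 5 of 29 members falling adjusted over the list alone, 0 over all genes in edgeR (9 at an unadjusted p below 0.05, 2 by DESeq2) and 14 near the free-RNA level. Macrophage lists were also lower in T or NK-like cells. M2-like genes stood at a median of −0.45 (12 of 13 near the free-RNA level), M1-like genes at −0.32 (6 of 13) and MHC class II at −0.32 (7 of 7). Camera gave them adjusted p = 2.64e-05, 0.000146 and 0.00986, and adjusted p = 0.21, 0.326 and 0.694 with an estimated correlation. After free-RNA subtraction the MHC class II list turned upward. In endothelial-like cells NF-kB target genes were lower (adjusted p = 1.92e-08, and adjusted p = 0.247 with an estimated correlation), with Nfkbia at −0.55 ± 0.14 and 8 members near the free-RNA level. There 1 of 27 members fell adjusted over the list alone and 0 over all genes in edgeR (5 at an unadjusted p below 0.05, 0 by DESeq2). Beside it MHC class II stood at a median of −0.86 (7 of 7 near the free-RNA level), M1-like genes at −0.81 (7 of 12) and M2-like genes at −0.57 (7 of 9), with adjusted p = 2.43e-08, 1.07e-07 and 0.00045, and adjusted p = 0.247 each with an estimated correlation. In neutrophil-like cells epithelial genes were higher (adjusted p = 3.24e-11, and adjusted p = 0.338 with an estimated correlation), with 2 of 8 members rising over all genes and 6 adjusted over the list alone, and all 8 were near the free-RNA level. The mitochondrially encoded list was higher there too (median 0.48, adjusted p = 4.81e-11, and adjusted p = 0.338 with an estimated correlation), with 9 of 11 members rising adjusted over the list alone and 0 over all genes in edgeR (9 at an unadjusted p below 0.05, 0 by DESeq2).

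Pgk1 was not lower in libraries labelled shPgk1. If free RNA from other cells hid a lower level in tumour-like cells, subtraction should bring the log2 fold below −0.5, and it gave 0.429 ± 0.174. If the labels of the groups were exchanged with a knockdown of at least 2-fold, the fold should reach 1, and it stayed below that with 2 standard errors added, at 0.777. A smaller knockdown with exchanged labels, recovery of expression in the cells that grew, and reads of near-identical copies counted as Pgk1 stay open and were not tested.

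Gm14015, a lincRNA on chromosome 2 (106463823 to 106523103 on the minus strand, GRCm38), stood at 37.6, 22.4 and 21.9 CPM in shNC and at 0.0652, 0.213 and 0.0241 CPM in libraries labelled shPgk1. Free RNA spread from tumour-like cells would leave other classes well below them, and their median level was 0.945 of the tumour-like level in the lowest shNC library, while a variant of the host animals would leave tumour-like cells low, and they stood at 0.890 of the others in the lowest library. A background spread over barcodes, from no cell class, predicted a ratio of at least 1.3 between the shallowest and the deepest cells of a class, and the median ratio was 1.89, against 1.41 for markers of other cell types and 0.852 for own markers. Markers of other cell types, which measure free RNA, also passed 1.3, so this ratio cannot tell a source in no cell class from free RNA. Gm14015 stood only slightly above them in monocyte or macrophage-like cells of shNC library 3 (1.446 and 1.428). A contaminant of the shNC preparations thus stays open. Since Gm14015 marks each shNC library and none labelled shPgk1, a difference in preparation would coincide with the groups. Differences between the groups cannot be told apart from such a difference. The source of Gm14015 and an effect of the hairpin were not tested. The erythroid markers Hba-a1 and Hbb-bs were also counted mainly in the shNC libraries, but unevenly over classes. Hbb-bs stood at 4.88, 4.53 and 8.20 CPM in shNC and at most at 0.240 CPM in libraries labelled shPgk1. Other transcripts were tied to single libraries, such as Ankfn1 at 42.5 CPM in shNC library 1 and Mcc at 52.0 CPM in shNC library 3.

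Xist, the noncoding RNA that silences an X chromosome (X, 103460366 to 103483254 on the minus strand, GRCm38), stood at 186, 204 and 0.136 CPM in shNC and at 185, 92.8 and 104 CPM in libraries labelled shPgk1. Male cells in shNC library 3 would bring Y-linked transcripts, and Kdm5d and Uty together reached 0.117 CPM (6 counts, upper limit 0.255) in its 6 non-tumour classes, and 0.390 CPM (2 counts, upper limit 1.41) in T or NK-like cells, where the test was first run. A set level of 1 CPM was not reached, but Eif2s3y, the other gene of that test, is not among the listed genes. No library of known male cells gives the level to be met. Over all cells Uty had 11 counts in shNC library 3 (0.125 CPM) and 10, 7, 2, 10 and 5 in the others (at most 0.0914 CPM). Kdm5d had 1 count in shNC library 3 and 0 to 2 in the others, so these genes did not set that library clearly apart. Y-linked Ddx3y stood at 62.0 CPM in this library and between 45.4 and 54.3 CPM in the others. It was counted in all 7 tested classes of each library, so its presence alone does not tell male cells. In T or NK-like, endothelial-like and fibroblast-like cells it stood at 70.1, 70.0 and 69.0 CPM there, against at most 52.7, 43.15 and 57.6 CPM elsewhere. In monocyte or macrophage-like and neutrophil-like cells it stood at 60.5 and 99.4 CPM, against at most 52.1 and 96.1 CPM. In conventional dendritic-like (46.4 CPM) and tumour-like cells (61.0 CPM) it lay within the range of the other libraries. For want of a level to be met, male cells are not excluded. A single X chromosome in the non-tumour cells may lower genes that escape silencing, whose median ratio to the other libraries was 0.763, but tumour-like cells had 0.799, so this stays open.

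The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, the number of splits with a count as large, the real one included, was 1 for all cells (3250, highest other 0), 1 for T or NK-like (19 and 1), 2 for dendritic-like (3 and 7), 1 for endothelial-like (5 and 1), 1 for epithelial tumour-like (1422 and 0), 1 for fibroblast-like (4 and 1), 1 for monocyte or macrophage-like (112 and 0) and 1 for neutrophil-like cells (7 and 0), and 1 for genes that depended on the class (403 and 0). For lists it was 2 for all cells (13 and 13), 3 for T or NK-like (10 and 10), 3 for dendritic-like (7 and 9), 1 for endothelial-like (13 and 12), 5 for epithelial tumour-like (10 and 12), 3 for fibroblast-like (9 and 16), 6 for monocyte or macrophage-like (6 and 16) and 6 for neutrophil-like cells (4 and 9). These lists were called with the preset correlation of 0.01, and why other splits gave more of them was not tested.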
